A study of Solanum lycopersicum with 18 samples.

How the data were processed

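Total RNA of tomato leaves was labelled with biotin and hybridised to the Affymetrix Tomato Genome Array, as the labels describe. The values analysed were the deposited log2 signals, which the authors made with RMA, a method that corrects background, normalizes arrays by quantiles and summarizes the probes of a probe set. Its version was not given in the sources used here. The table held 8664 probe sets on 18 arrays. The 82 probe sets of the manufacturer's controls were left out of the tests and read separately, which left 8582 probe sets. No further scaling, filter or pseudocount was applied.

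Gene symbols came from the annotation of the array platform. A single symbol was given for 766 probe sets, covering 697 genes, and 7816 probe sets had no symbol, so that 8.93% of the tested probe sets could be named. Gene identifiers were matched to the tomato gene table of assembly SLM_r2.1 for their synonyms, and 751 named probe sets matched. Of the named probe sets, 624 had an informative symbol and the others only a locus number. For 53 genes there was more than 1 probe set, and for 2 of these, LOC543955 and LOC544138, the probe sets were called in opposite directions in at least 1 inoculation comparison.

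Group means were fitted per probe set over all 18 arrays with limma 3.58.1 in R 4.3.3, and the contrasts were tested with its moderated statistics and default settings. The p-values were adjusted per contrast by the method of Benjamini and Hochberg, and a probe set was called when its adjusted p was under 0.05. The 10 contrasts were NPA against water at each of the 3 times, NPA against water averaged over the times, each inoculated group against the uninoculated group of the same pretreatment, and the interaction of pretreatment and inoculation at 6 and at 12 hpi. Each p measures the spread between arrays, each a pool of plants. Without a block that spread also holds differences by replicate number, which water and NPA arrays share. Residual degrees of freedom were 12. The median standard error of a contrast of 3 against 3 arrays was 0.168 on the log2 scale.

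The replicate numbers of the titles were tested as pairing before use. After subtracting group means, arrays of the same number correlated with a median r of 0.433 over 45 pairs of arrays, and the lowest of these was 0.126. Arrays of different numbers had a median r of −0.229 and a highest r of 0.181. Each of the 18 arrays had its best match in another group at its own number. Arrays of the same number and time had a median r of 0.755. Replicate number was therefore also fitted as a block over all arrays, and, chosen after the data were seen, as a block within each time, where NPA is compared with water inside each pair. The median standard error was 0.122 with the first block and 0.086 with the second, which had 6 residual degrees of freedom.

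Gene lists were written from symbols for 21 groups, and 17 of them had at least 5 measured genes. The list named for histones and cell cycle holds no histone gene. Together they held 189 genes. The plan also matched lists on gene names and descriptions, but only symbols and their synonyms were matched. ER1, PR-P2 and FESOD, for example, stand in no list, and each list result covers its matched genes only. A gene with several probe sets entered by the probe set with the highest mean. Lists were tested with camera of limma, with its preset correlation between genes of 0.01, and p-values were adjusted over the 17 lists within a contrast. Each list was tested again with an estimated correlation, and with fry, which asks whether the genes of a set move on balance in one direction. Of the 25 list calls, the wound list in the interaction at 12 hpi was the single one that held with an estimated correlation, at an adjusted p of 0.0354. The lists for salicylic acid, abscisic acid, trichomes and vascular tissue had fewer than 5 genes, and their members are given as values or calls only.

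Named genes followed a rule. In each contrast, among called probe sets with an informative symbol and no overlap between the compared groups, the 10 largest rises and the 10 largest falls were named, with 1 probe set per gene. For the averaged and interaction contrasts the number was 5 each way, without the requirement of no overlap. Where fewer than 5 genes passed, the 5 named genes with the smallest p were given as values. Up to 4 members of each list, those with the smallest p, were added as values. Exceptions are the list members named for a direction opposite to their list, the genes of the block within time at 12 hpi, the light-harvesting genes and the probe sets called by a single alternative, all chosen after their values were seen.

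The contrasts, lists, naming rule, thresholds and other settings were chosen before the data were examined, except that the lists were then matched on symbols and synonyms alone. These settings were a fit of only the groups compared, the replicate block, cyclic loess, median centring, leaving out the dimmest 30% of probe sets, a trended and robust prior, array weights, leaving out probe sets with an _x_at, _s_at or _a_at suffix (234), a fold change of at least 2, and leaving out each array in turn, and for the lists an estimated correlation, the mean over the probe sets of a gene, and fry. The same fit was tested on simulated data with 200 changed probe sets. Between NPA and water at 12 hpi it recovered 40.3%, 79.1% and 98.5% of probe sets changed 1.5-fold, 2-fold and 4-fold, with 0 unchanged probe sets called. With the block within time the shares were 86.6%, 98.5% and 100%, with 10 unchanged probe sets called. The simulated spread was drawn independently for each probe set, so probe sets did not vary together. These shares and false calls need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.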

Results

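Leaves of the tomato cultivar Summer sweet were sprayed with water or with NPA, phosphorous acid at 1 g/L brought to a near neutral pH with potassium hydroxide. Phosphonates of this kind are used against oomycete diseases. After 3 days the plants were inoculated with zoospores of Phytophthora parasitica, an oomycete pathogen, and kept in a moist chamber. Leaves were taken at 3 days post treatment (3 dpt) without inoculation, and at 6 and 12 hours post inoculation (6 and 12 hpi). Each of the 6 groups had 3 arrays, and each array carried RNA pooled from 5 plants. A label field gives 3 hours after treatment where titles and design give 3 days, and 3 days was used. No group was left uninoculated in the moist chamber, so each inoculation comparison also holds the change of humidity and of clock hour.

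The log2 signals ran from 2.73 to 14.83, and the array medians lay between 9.05 and 9.12. Water and NPA arrays of the same time and replicate number correlated across probe sets with r between 0.987 and 0.996. Between 3 dpt and 12 hpi r was 0.622 to 0.746. The number of arrays limits the precision, and the median 95% confidence interval of a contrast reached 0.359 on the log2 scale to either side. The 3′ minus 5′ signal of control probe sets for GAPDH and actin is read as a sign of RNA quality. For GAPDH it was 0.46 ± 0.089 (log2, SD, n = 3) in water leaves at 3 dpt, 0.707 ± 0.06 at 6 hpi and 0.727 ± 0.032 at 12 hpi. In NPA leaves it was 0.40 ± 0.098, 0.693 ± 0.021 and 0.863 ± 0.006. For actin it did not move the same way, at 0.08 ± 0.09, 0.03 ± 0.156 and −0.027 ± 0.153 in water leaves and 0.09 ± 0.066, −0.01 ± 0.062 and −0.093 ± 0.095 in NPA leaves, with overlapping arrays of NPA and water at each time.

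The response of water-pretreated leaves to the pathogen was asked by comparing inoculated with uninoculated leaves. At 6 hpi LOC543878 (PR5), a pathogenesis-related protein of the thaumatin family, was 363-fold higher (log2 8.50 ± 0.51, SE, n = 3 and 3 arrays, limma adjusted p = 6.03e-09). DES, a divinyl ether synthase that makes oxylipins, was 156-fold higher (log2 7.28 ± 0.52), and ER1, an ethylene-responsive proteinase inhibitor, 93.5-fold higher (6.55 ± 0.30). Among named genes the largest fall was that of CO1, a CONSTANS-type regulator of light and daylength responses, 40.5-fold lower (log2 −5.34 ± 0.20, adjusted p = 5.59e-11). Over all probe sets the largest fall was −8.58. CrtR-b1, a beta-carotene hydroxylase, was 29.7-fold lower, Psy1, a phytoene synthase, 27.7-fold lower, and CCD1B, a carotenoid cleavage dioxygenase, 12.7-fold lower. Without water replicate 2 of 6 hpi DES was 242-fold higher.

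Further large rises of named genes at 6 hpi were GluB, a beta-1,3-glucanase (70.2-fold), PTI5, an ethylene-response transcription factor that binds the Pto kinase (59.7-fold), and NP24-I, an osmotin-like protein (44.4-fold). THT1-3, which makes hydroxycinnamoyl amides, rose 35.8-fold, the transcription factor NAC1 34.5-fold, TSI-1 29.4-fold and PR-P2, of the PR4 family, 26.2-fold. Among the falls were fsm1 (18.5-fold lower), GA20OX1, a gibberellin 20-oxidase (14.6-fold lower), the chalcone synthases CHS2 and CHS1 of flavonoid synthesis (13.1-fold and 12.9-fold lower), LOC543809 (INS-1P) (11.8-fold lower) and PCNA, a DNA replication clamp (11.3-fold lower). Without water replicate 2 of 3 dpt GluB was 38-fold higher, without replicate 1 of 3 dpt NAC1 58.1-fold higher, and without replicate 2 of 6 hpi GA20OX1 25.8-fold lower. For each of these 20 genes every inoculated array lay beyond every uninoculated one, which was a condition for naming them. In all, limma called 4821 of 8582 probe sets, 2373 higher and 2448 lower, or 56.2%, and 1998 of them changed at least 2-fold.

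Of the 12 genes of pathogenesis-related proteins, 9 rose, 1 fell and 2 did not pass at 6 hpi, with a median of 3.17 on the log2 scale. Adjusted over the list alone, 10 rose and 1 fell. PR1b1 rose by 4.37 ± 0.57, the chitinases CHI9 and CHI3 by 4.41 ± 0.58 and 3.08 ± 0.39, and P69A, a subtilisin-like protease, fell by 0.36 ± 0.11. The camera test put the list above the other genes (adjusted p = 0.0021, and adjusted p = 0.409 with an estimated correlation). Ethylene genes rose in 19 of 30 cases, fell in 1 and did not pass in 10 (20 and 1 adjusted over the list alone, median 1.13). Their adjusted p was 4.40e-04, and adjusted p = 0.409 with an estimated correlation. Beside PTI5, the response factor EREB rose by 2.98 ± 0.29, the synthesis gene ACS2 by 2.37 ± 0.47 and the signal transducer EIL3 by 2.24 ± 0.21, while ERF-H1 fell by 0.96 ± 0.38.

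Other lists did not pass as groups by camera at 6 hpi, though many of their members did. In defence signalling 6 of 10 genes rose and 2 fell (median 0.97, adjusted p = 0.1639), with the kinase MPK3 at 3.03 ± 0.67, the transcription factor WRKYIId-4 at 2.87 ± 0.31 and WRKY2 at 1.65 ± 0.14. The sugar and sink list had 4 of 7 genes rising and 1 falling, among them HT2, a hexose transporter, at 4.38 ± 0.47 and Wiv-1, a cell wall invertase, at 3.04 ± 0.34. In the redox list 6 of 12 rose and 5 fell. The NADPH oxidase Wfi1 rose by 4.53 ± 0.69, the peroxidase CEVI-1 by 3.25 ± 0.33 and the glutathione transferase GST-T4 by 3.00 ± 0.25, while the catalase CAT2 fell by 1.06 ± 0.19. The jasmonate synthesis list split into 4 rising and 4 falling genes. AOS, an allene oxide synthase, rose by 4.58 ± 0.52 and AOC, the next enzyme, fell by 1.18 ± 0.20. Its median (0.06) and mean (0.35) were above 0 while camera pointed down (adjusted p = 0.9436). Members of that list that serve other oxylipin branches are HPL and loxC, of leaf volatiles, and TomloxE. Wound and jasmonate defence proteins rose in 3 of 6 cases, with CEVI57, a proteinase inhibitor, at 4.37 ± 0.83.

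The same comparison was made at 12 hpi. In water leaves DES was then 695-fold higher than at 3 dpt (log2 9.44 ± 0.52, n = 3 and 3 arrays, limma adjusted p = 5.78e-10), LOC543878 (PR5) 665-fold, CEVI57 579-fold (9.18 ± 0.83) and ER1 432-fold (8.75 ± 0.30). CAB5, a chlorophyll a/b binding protein of the light-harvesting antenna, was 272-fold lower (log2 −8.09 ± 0.20, adjusted p = 2.83e-13). ZEP, the zeaxanthin epoxidase of carotenoid metabolism, was 83.1-fold lower, and CIP1 113-fold lower. XTH7, a xyloglucan endotransglucosylase, was 53.6-fold lower and the expansin EXP2 42.2-fold lower. The exact size of the largest folds is uncertain, since some signals lay towards the ends of the range of 2.73 to 14.83. In water leaves at 3 dpt LOC543878 (PR5) lay at 3.91 to 5.97, CEVI57 at 4.03 to 4.36 and CAB5 at 14.03 to 14.13, and at 12 hpi LOC543878 (PR5) lay at 14.07 to 14.3.

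Also among the largest rises of named genes at 12 hpi were TSI-1 (253-fold), PTI5 (183-fold), NP24-I (158-fold), GluB (152-fold), PR1b1 (116-fold) and PR-P2 (115-fold). Without water replicate 2 of 3 dpt GluB was 82-fold higher. The other largest falls among named genes were GA20OX1 (63.1-fold lower), CO1 (55.1-fold lower), CHS2 (45.2-fold lower), the lipid transfer protein ltpg1 (41-fold lower) and fsm1 (34.7-fold lower). Over all probe sets the largest fall was −9.15 on the log2 scale. Called probe sets numbered 5911, 3198 higher and 2713 lower, which is 68.9%, and 3189 changed at least 2-fold. Of the 2373 probe sets higher at 6 hpi 2119 were also higher at 12 hpi, and of the 2448 lower ones 1924 were also lower. Independent calls would share 884 and 774. Both comparisons use the same uninoculated arrays, which alone gives their log2 changes an r of 0.498 in 100 simulated draws, against 0.885 measured across probe sets. The covariance of the 2 changes was 1.761 measured and 0.031 in those draws, so the shared arrays account for a small part of it. Of the probe sets called in either direction at 6 hpi, 37 that were higher were lower at 12 hpi, and 36 the reverse.

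**Figure D1:**
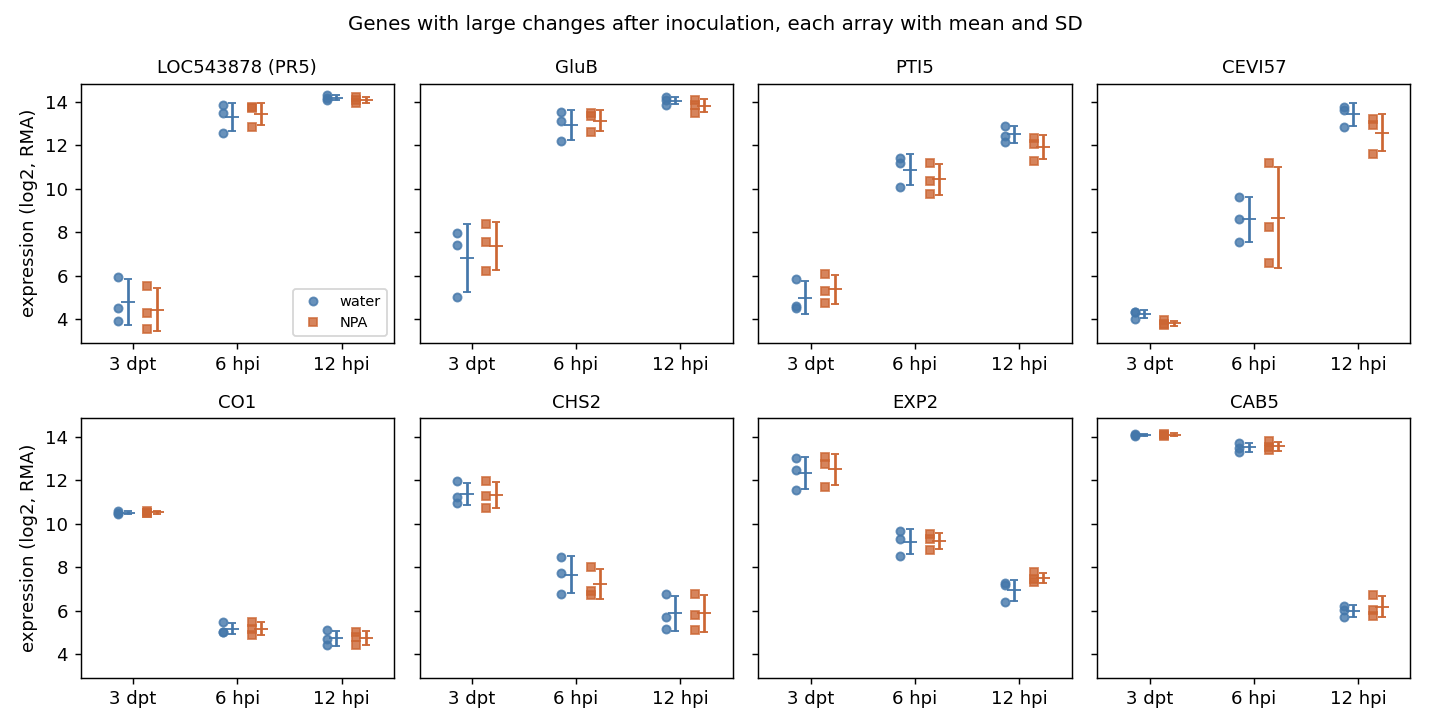
Log2 signal of 8 genes at 3 dpt, 6 hpi and 12 hpi, with a point for each array of water (blue circles) and NPA leaves (orange squares) and the mean with SD of the 3 arrays beside them. In water leaves CAB5 lies at −0.57 against its uninoculated level at 6 hpi and at −8.09 at 12 hpi, while LOC543878 (PR5) is 8.50 higher at 6 hpi.

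All 12 genes of pathogenesis-related proteins passed at 12 hpi, 10 higher and 2 lower (10 and 2 adjusted over the list alone, median 5.49). Among them P4, of the PR1 family, rose by 6.23, CHI14 by 5.07 and the protease P69B by 4.52, while P69A fell by 1.88 and the chitinase CHI17 by 1.14. The list's adjusted p was 0.0059, and adjusted p = 0.3991 with an estimated correlation. Ethylene genes rose in 23 of 30 cases and fell in 3 (24 and 3 adjusted over the list alone, median 1.34, adjusted p = 0.0013, and adjusted p = 0.3991 with an estimated correlation). ACS2 rose by 4.55, the receptor ETR4 by 3.66 and LOC606712 (erf1a) by 3.54, and the receptor ETR6 fell by 1.26.

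Photosynthesis genes fell in 7 of 8 cases at 12 hpi (7 adjusted over the list alone, median −1.03, adjusted p = 0.0013, and adjusted p = 0.3991 with an estimated correlation). CAB4 and CAB6A fell by 5.07 and 4.97 and the photosystem II protein PSBP by 1.23, while PSBR was at 0.14. At 6 hpi only CAB5 of this list had passed over all genes, with a fall of 0.57 ± 0.20, and no member adjusted over the list alone. That call of CAB5 was lost without water replicate 2 (adjusted p = 0.0529) or 3 (0.0633) of 3 dpt and without water replicate 1 (0.0578) or 3 (0.0952) of 6 hpi. Cell wall genes fell in 20 of 32 cases and rose in 7 (the same numbers adjusted over the list alone, median −2.18). Their adjusted p was 0.0039, adjusted p = 0.3991 with an estimated correlation, and 0.1503 with the dimmest probe sets left out. The fallers included the endoglucanase CEL8 (−4.32), EXP5 (−4.40) and LOC543916 (LeXTH9) (−4.25). The beta-galactosidases TBG3 and TBG4 and the pectin methylesterase PMEU1 rose by 5.18, 3.63 and 3.05. At 6 hpi 18 cell wall genes had fallen and 6 had risen, and the list did not pass (adjusted p = 0.1639).

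The sugar list had 6 of 7 genes rising at 12 hpi (median 2.04, adjusted p = 0.1539), with HT2 at 5.52, Wiv-1 at 4.35 and the sucrose synthase sus3 at 2.35, while LIN8, an invertase, fell by 2.09. In defence signalling 6 of 10 rose and 2 fell (adjusted p = 0.3419), and in the wound list 4 of 6 rose (adjusted p = 0.2524). Redox genes rose in 6 of 12 cases and fell in 4. Jasmonate synthesis genes rose in 2 and fell in 5 of 9 cases, with AOS at 3.27 and AOC at −2.24. Phenylpropanoid genes split evenly at both times, 3 rising and 3 falling of 7. THT1-3 rose by 5.76 at 12 hpi and CCR1 of lignin synthesis fell by 2.94. The list's median at 12 hpi was 0.17, while its mean (−0.46) and its test pointed down (adjusted p = 0.8868). In the terpenoid and sterol list 4 of 5 genes fell at 12 hpi and 3 of 5 at 6 hpi, of which GABA-TP2 and gad2 act in the metabolism of gamma-aminobutyrate. Of the other 3 genes, SSTLE1 and FPPS1, a farnesyl diphosphate synthase, fell at 12 hpi and FPPS1 at 6 hpi, too few for a test as a group. The list's adjusted p was 0.2524 at 12 hpi and 0.1865 at 6 hpi. HMGR, of sterol synthesis, rose by 0.91 at 12 hpi. Heat shock genes moved both ways, 2 up and 3 down of 7 at 12 hpi and 2 up and 2 down at 6 hpi. The list's median (0.30) and test pointed up at 6 hpi while its mean was −0.19. The rise of HSC80 at 6 hpi was lost without water replicate 1 (adjusted p = 0.0963) or 2 (0.0772) of 3 dpt or water replicate 3 of 6 hpi (0.0946), and after cyclic loess (0.0599). That of HSP17-6 at 12 hpi was lost without water replicate 1 (0.107) or 3 (0.0506) of 3 dpt or water replicate 2 of 12 hpi (0.0862), and after cyclic loess (0.0704). NPR1, a regulator of salicylic acid responses, rose by 0.80 and 1.17 at the 2 times, and the call at 6 hpi was lost without water replicate 2 of 3 dpt (0.0566) or water replicate 1 (0.066) or 3 (0.0766) of 6 hpi. No other list passed as a group by camera at 12 hpi. The GAPDH 3′ minus 5′ difference was 0.46 at 3 dpt and 0.707 and 0.727 at these times.

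NPA-pretreated leaves were compared in the same way after inoculation. At 6 hpi LOC543878 (PR5) was 508-fold higher than in uninoculated NPA leaves (log2 8.99 ± 0.51, n = 3 and 3 arrays, limma adjusted p = 3.79e-09), DES 192-fold, ER1 87.8-fold, NP24-I 54.6-fold and GluB 54.2-fold. TSI-1 rose 41.9-fold, PTI5 33.3-fold, CEVI57 29-fold, Eix1, a receptor of the fungal elicitor xylanase, 22.1-fold and NAC1 21-fold. Without NPA replicate 1 or 2 of 6 hpi CEVI57 was 12.1-fold or 59.4-fold higher, and without NPA replicate 1, 2 or 3 of 3 dpt NAC1 was 54.4-fold, 12.9-fold or 13.2-fold higher. CO1 was 40.4-fold lower, CrtR-b1 32.8-fold, Psy1 27.5-fold, fsm1 19.9-fold, CHS2 17.2-fold and TIP, a tonoplast intrinsic protein, 14.2-fold lower. GA20OX1 fell 13.4-fold, CCD1B 12.6-fold, LOC543809 (INS-1P) 11.8-fold and CHS1 10.6-fold. The count was 4630 probe sets, 2356 higher and 2274 lower.

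By 12 hpi in NPA leaves LOC543878 (PR5) was 792-fold higher (log2 9.63 ± 0.51, adjusted p = 5e-10), DES 453-fold, CEVI57 433-fold, ER1 286-fold, TSI-1 151-fold and NP24-I 131-fold. PTI5 rose 92.2-fold, FESOD, an iron superoxide dismutase, 90.7-fold, GluB 86.8-fold and PR1b1 50.6-fold. CAB5 was 240-fold lower (log2 −7.91 ± 0.20), CIP1 97-fold, ZEP 76.1-fold, GA20OX1 61.7-fold and CO1 54.9-fold lower. The remaining large falls of named genes were ltpg1 (45.8-fold), CHS2 (43.5-fold), the carbonic anhydrase ca2 (34-fold), CAB4 and XTH7 (32.5-fold each). Called probe sets numbered 5854, 3174 higher and 2680 lower. Changes of at least 2-fold numbered 1937 at 6 hpi and 3032 at 12 hpi.

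In NPA leaves pathogenesis-related genes rose in 8 of 12 cases at 6 hpi (9 adjusted over the list alone, adjusted p = 0.0031, and adjusted p = 0.4423 with an estimated correlation) and at 12 hpi rose in 10 and fell in 2 (the same adjusted over the list alone, adjusted p = 0.0128, and adjusted p = 0.4815 with an estimated correlation). The list's median was 4.35 at 12 hpi, and its adjusted p there was 0.0644 with the dimmest probe sets left out. Ethylene genes rose in 19 of 30 cases and fell in 2 at 6 hpi (adjusted p = 2.88e-04, and adjusted p = 0.381 with an estimated correlation), and rose in 24 and fell in 2 at 12 hpi (adjusted p = 0.0015, and adjusted p = 0.4334 with an estimated correlation). Adjusted over the list alone the ethylene counts were 20 and 2, and 24 and 2. Photosynthesis genes fell in 7 of 8 cases at 12 hpi (7 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.4334 with an estimated correlation). Cell wall genes fell in 20 of 32 cases and rose in 7 at 12 hpi (the same adjusted over the list alone, median −1.77, adjusted p = 0.0128). That list had adjusted p = 0.4334 with an estimated correlation, and 0.3505 with the dimmest probe sets left out. In the wound list 3 of 6 rose at 12 hpi and TD2, a threonine deaminase, fell by 1.97, while at 6 hpi CEVI57 was the single member to rise. LAPA2 of that list, at 0.33, passed at 6 hpi with the replicate block (adjusted p = 0.00289), with array weights (0.0214) and without NPA replicate 2 of 6 hpi (0.0429). Without NPA replicate 3 of 3 dpt TD2 was at −1.24 at 12 hpi and did not pass (adjusted p = 0.0846), and without replicate 1 of 3 dpt it was at −2.71. The other lists did not pass as groups by camera in NPA leaves at either time. The GAPDH 3′ minus 5′ difference in these leaves was 0.40 at 3 dpt and 0.693 and 0.863 at 6 and 12 hpi.

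**Figure D2:**
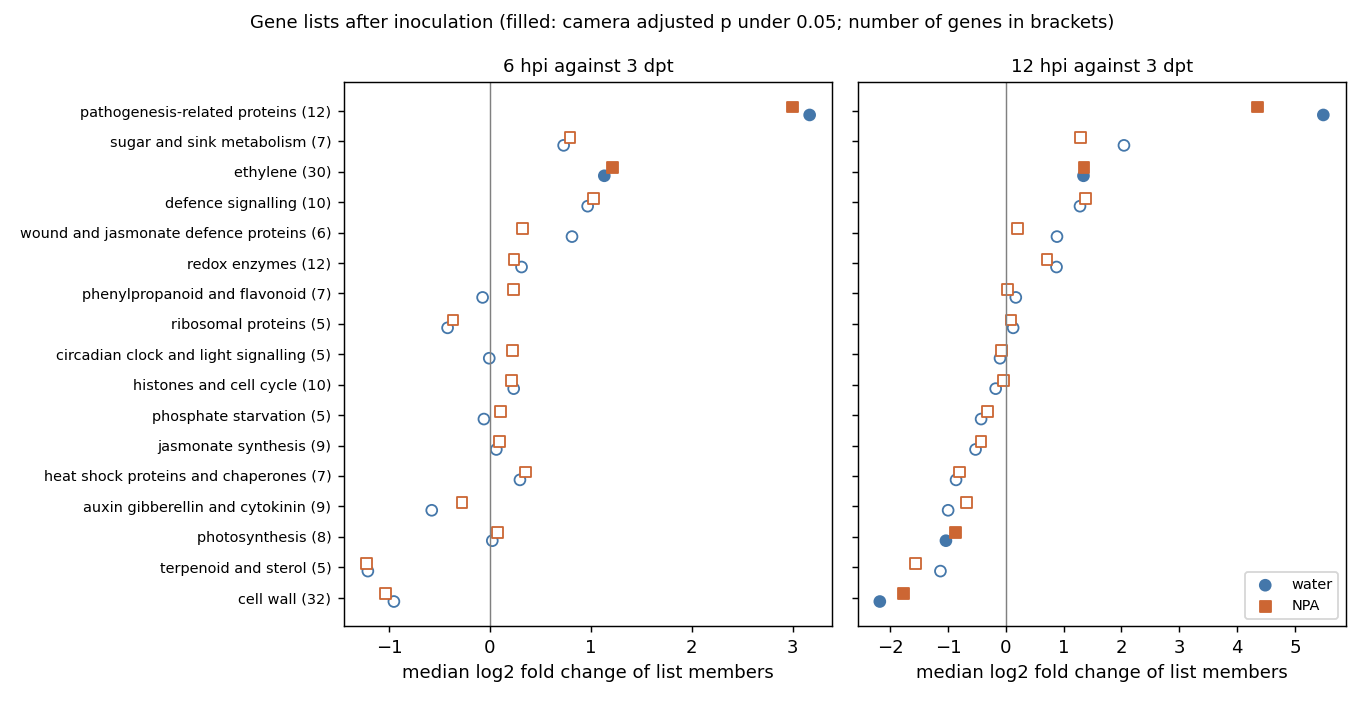
Median log2 fold change of the 17 tested gene lists at 6 and 12 hpi against 3 dpt in water and NPA leaves, with the number of genes of each list in brackets. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation, and the largest median in water leaves is that of pathogenesis-related proteins at 12 hpi, 5.49.

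The water and NPA responses overlapped widely. At 6 hpi 2143 of the 2373 probe sets higher in water leaves were also higher in NPA leaves (90.3%), and 2133 of the 2448 lower ones were also lower (87.1%), where independent calls would share 651 and 649. At 12 hpi the shared numbers were 2927 (91.5%) and 2514 (92.7%). Calls in opposite directions numbered 0 at both times. Across probe sets, which are not independent replicates, the log2 changes of NPA and water leaves correlated with r = 0.984 at 6 hpi and 0.988 at 12 hpi. These pairs of changes share no array. Water and NPA arrays of the same time and replicate number still vary together, with a median r of 0.755 after subtracting group means. Some overlap and an r above 0 would thus arise without a response, and no value that keeps the pairing was computed.

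Whether NPA alone altered the leaf was asked at 3 dpt. Among named genes, LAPA1, a wound-induced leucine aminopeptidase, was 2.09-fold higher in NPA leaves (log2 1.06 ± 0.32, n = 3 and 3 arrays) but did not pass (limma adjusted p = 1). The pathogenesis-related genes PR-5 and CHI3 stood at 0.54 ± 0.22 and 0.96 ± 0.39, the peroxidase CEVI-1 at 0.69 ± 0.33 and the autophagy gene ATG6 at −0.24 ± 0.12, all with an adjusted p of 1. P4 and PR1b1 stood at 1.31 ± 0.74 and 1.01 ± 0.57. limma called 0 probe sets, with 50 (0.58%) at an unadjusted p under 0.05, and 0 were called with either replicate block. Chance alone would give a share near 0.05, which is more, so the fit without a block is conservative here. With the block within time, chosen after the data were seen, 495 had an unadjusted p under 0.05. The 95% interval lay within 2-fold either way for 92.4% of probe sets.

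As groups at 3 dpt, 2 lists stood higher in NPA leaves. Pathogenesis-related genes had a median of 0.54 with 0 of 12 members passing (0 adjusted over the list alone, camera adjusted p = 8.04e-04, and adjusted p = 0.748 with an estimated correlation), and the list mean was above 0 in 3 of 3 replicate numbers, at 0.15, 0.47 and 0.58. The means of phenylpropanoid, phosphate starvation and sugar genes, lists that did not pass, were also above 0 in 3 of 3. The pathogenesis-related call was lost without water replicate 2 (adjusted p = 0.6602), water replicate 3 (0.1643) or NPA replicate 1 (0.7184). Wound and jasmonate defence genes had a median of 0.44 with 0 of 6 passing, and 1 was higher in NPA leaves adjusted over the list alone. Their adjusted p was 0.0011, adjusted p = 0.088 with an estimated correlation and 0.1926 with the block within time. List means were 0.27, −0.04 and 1.10, so 2 of 3 were above 0, and the call was lost without water replicate 1 (0.1483) or NPA replicate 3 (0.2426). Phosphate starvation genes, listed because phosphonate resembles phosphate, had 0 of 5 passing, with a median of −0.13, a mean of 0.11 and a test pointing up (adjusted p = 0.911).

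How NPA altered the leaf after the pathogen had arrived was asked at 6 and 12 hpi. At 6 hpi the named genes with the smallest p were the protease P69A (0.35 ± 0.11 higher in NPA leaves), the ascorbate peroxidase APX1 (0.36 ± 0.12), the cysteine protease VPE5 (0.43 ± 0.15), the ribonuclease RNALE (0.80 ± 0.33) and AOS (−1.24 ± 0.52), all with a limma adjusted p of 1. limma called 0 probe sets, with 84 (0.98%) at an unadjusted p under 0.05 and 0 with either replicate block, and for 90.8% of probe sets the 95% interval lay within 2-fold either way. With the block within time 877 had an unadjusted p under 0.05, so a difference at this time is not excluded. The list named for histones and cell cycle, which holds no histone gene, stood lower as a group in NPA leaves, with a median of −0.21 and 0 of 10 passing (0 adjusted over the list alone, adjusted p = 0.0032, and adjusted p = 0.3582 with an estimated correlation). The list means were −0.26, −0.49 and −0.02, below 0 in 3 of 3. Those of jasmonate synthesis, terpenoid and defence signalling genes, which did not pass, were also below 0 in 3 of 3. Members of the cell cycle list were the kinase CDKB2 at −0.61 and the cyclins CycA2 and CycA1 at −0.55 and −0.53. NSY at −0.40 acts in carotenoid synthesis, and without it the adjusted p was 0.0151. The call was lost without water replicate 1 (0.0567) or water replicate 2 (0.2416).

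At 12 hpi 6 lists differed between NPA and water leaves, with small medians. Cell wall genes stood higher in NPA leaves, with a median of 0.20 over 32 genes and list means of 0.28, 0.08 and 0.24 by replicate number (adjusted p = 0.0024, and adjusted p = 0.3436 with an estimated correlation). Photosynthesis genes stood higher by a median of 0.15, with list means of 0.12, 0.20 and 0.07 (adjusted p = 0.0351, and adjusted p = 0.4145 with an estimated correlation). Lower in NPA leaves were wound and jasmonate defence genes (median −0.47, adjusted p = 0.0175, and adjusted p = 0.3055 with an estimated correlation), heat shock genes (median −0.42, adjusted p = 0.0308, and adjusted p = 0.3743 with an estimated correlation), pathogenesis-related genes (median −0.28, adjusted p = 0.0483, and adjusted p = 0.4145 with an estimated correlation) and sugar genes (median −0.29, adjusted p = 0.0483, and adjusted p = 0.3743 with an estimated correlation). In each of these 4 lists the mean was below 0 in 3 of 3 replicate numbers, for pathogenesis-related genes at −0.33, −0.40 and −0.20. The same sign in 3 of 3 was found for lists that did not pass. These were jasmonate synthesis, ethylene, phenylpropanoid, terpenoid, redox and ribosomal protein genes, so that sign does not set the called lists apart. No member passed over all genes, and adjusted over the list alone 1 wound gene and 1 terpenoid gene, FPPS1, were lower in NPA leaves. The GAPDH 3′ minus 5′ difference was 0.863 ± 0.006 in NPA and 0.727 ± 0.032 in water leaves at this time.

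Each of these 6 calls at 12 hpi was lost without at least 1 of the 6 arrays. The fit had no block, so leaving out 1 array also left its partner unpaired. These losses therefore cannot tell reliance on few arrays from broken pairing. The same holds for losses of list calls between NPA and water at the other times and in the interactions. The cell wall call was lost without water replicate 3 (adjusted p = 0.1477) or NPA replicate 1 (0.2044), and the wound call without water replicate 2 (0.0716) or NPA replicate 3 (0.1121). Heat shock was lost without water replicate 2 (0.4155), NPA replicate 1 (0.1949) or NPA replicate 3 (0.2123), and photosynthesis without water replicate 3 (0.5837), NPA replicate 1 (0.0661) or NPA replicate 2 (0.9433). The pathogenesis-related call was lost without water replicates 1, 2 or 3 (0.1059, 0.0716 and 0.0829) or NPA replicates 2 or 3 (0.4044 and 0.1497). The sugar call was lost without any of water replicates 1, 2 and 3 (0.125, 0.0716 and 0.0829) or NPA replicates 1, 2 and 3 (0.0968, 0.3904 and 0.0574). With the replicate block over all arrays the wound, photosynthesis and sugar lists had adjusted p of 0.0678, 0.077 and 0.1159, and with the block within time 0.1186, 0.011 and 0.1526. After cyclic loess the pathogenesis-related, photosynthesis and sugar lists each had 0.0604, and pathogenesis-related genes 0.0755 with the dimmest probe sets left out.

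**Figure D3:**
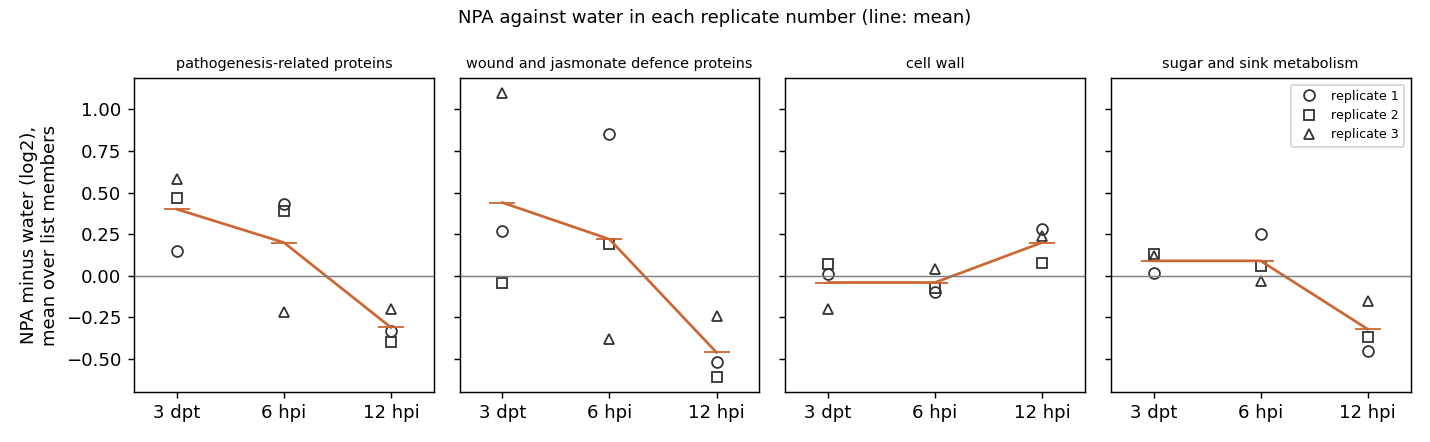
Mean log2 difference of NPA minus water leaves over the genes of 4 lists (pathogenesis-related, wound, cell wall, sugar) at 3 dpt, 6 hpi and 12 hpi, with a point for each replicate number and a line for their mean. Pathogenesis-related genes lie at 0.15, 0.47 and 0.58 at 3 dpt and at −0.33, −0.40 and −0.20 at 12 hpi.

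Single genes at 12 hpi were first tested without a block. LOC543602 (Eli3), of an elicitor-induced alcohol dehydrogenase family, was 2.5-fold lower in NPA leaves (log2 −1.32 ± 0.29, n = 3 and 3 arrays, limma adjusted p = 0.681), and FPPS1 1.68-fold lower (−0.75 ± 0.16, adjusted p = 0.681). Xegip, an inhibitor of fungal xyloglucanases, was at −1.09 ± 0.27, the cell death suppressor BI-1 at −0.39 ± 0.10 and LOC606710 (ppo), a polyphenol oxidase, at −0.71 ± 0.21. limma called 0 probe sets, with 270 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0533. For 90.2% of probe sets the 95% interval lay within 2-fold either way. With the replicate block over all arrays 4 were called, all lower in NPA leaves and chosen for naming after their values were seen. They were FPPS1 (adjusted p = 0.0337) and 3 probe sets without a gene symbol, at 3.12-fold lower (log2 −1.64 ± 0.205, adjusted p = 0.0211), 1.62-fold lower (−0.70 ± 0.107, adjusted p = 0.0435) and 1.57-fold lower (−0.65 ± 0.093, adjusted p = 0.0337).

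Comparing NPA with water inside each replicate pair at 12 hpi, a fit chosen after the data were seen, called 184 probe sets, 37 higher and 147 lower in NPA leaves. In this fit 1620 had an unadjusted p under 0.05. All 184 had the same sign in 3 of 3 pairs, which follows in large part from calling them on these pairs. The values that follow are differences between NPA and water leaves at 12 hpi and not changes after inoculation. By this fit HSP17.4, a small heat shock protein, was lower in NPA leaves by 1.15 ± 0.06 (adjusted p = 0.000141), LOC543602 (Eli3) by 1.32 ± 0.25, Xegip by 1.09 ± 0.18 and FPPS1 by 0.75 ± 0.09 (adjusted p = 0.012). ACS2, of ethylene synthesis, was lower by 1.33 ± 0.26, the mitochondrial small heat shock protein MTSHP by 1.16 ± 0.24, and the sugar genes HT2 and sus3 by 0.95 ± 0.17 and 0.95 ± 0.19. The glutamate dehydrogenase gdh1 was lower by 0.92 ± 0.16, the phospholipase PLDb1 by 0.60 ± 0.10, LOC543809 (INS-1P) by 0.58 ± 0.10 and ODC, an ornithine decarboxylase of polyamine synthesis, by 0.52 ± 0.07. Also lower in NPA leaves, by less, were UCP (0.41 ± 0.09), BI-1 (0.39 ± 0.06), Eix1 (0.38 ± 0.08), SAR2 (0.37 ± 0.08) and DHQS of the shikimate pathway (0.35 ± 0.07). EXP5 was higher in NPA leaves by 0.67 ± 0.13 (adjusted p = 0.037), the growth regulator TCP3 by 0.52 ± 0.10, TBG1 by 0.36 ± 0.07, CAB6A by 0.32 ± 0.06 and the transcription factor GBF12 by 0.31 ± 0.06. Without the pair of replicate 1, 2 or 3 the count was 4, 3 or 38. NPA and water arrays were also apart in the GAPDH 3′ minus 5′ difference at this time, 0.863 against 0.727, and overlapped in that of actin, −0.093 against −0.027.

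**Figure D4:**
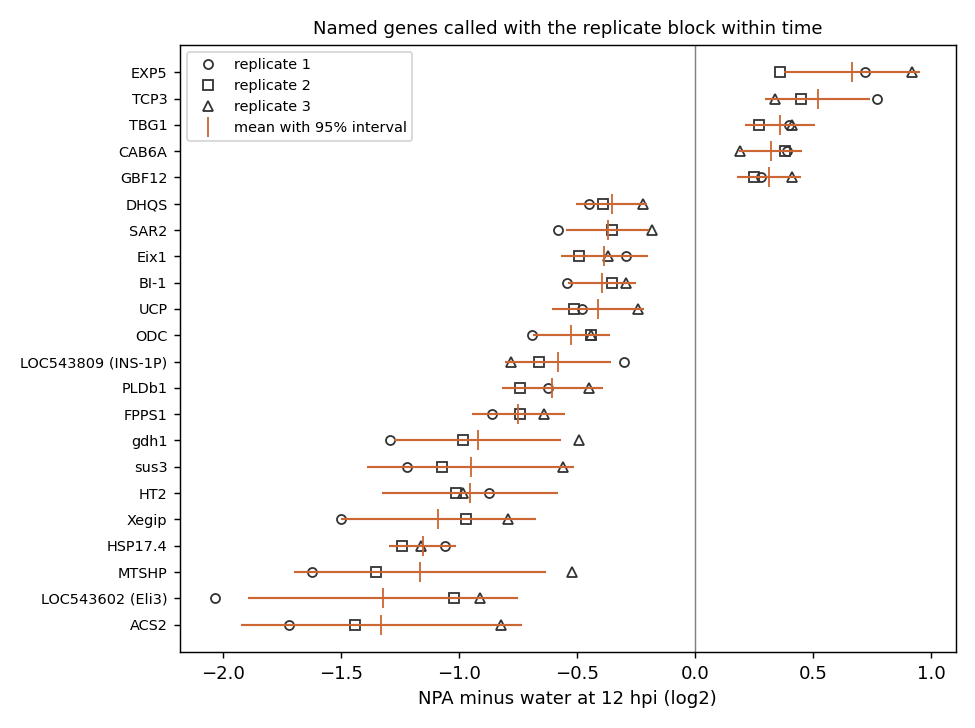
Log2 difference of NPA minus water leaves at 12 hpi for the 22 named genes called with the replicate block within time, with a point for each replicate pair and the mean with its 95% interval. Of these genes 5 lie above 0 and 17 below, and every point of a gene lies on the side of its mean.

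Averaged over the 3 times, NPA and water leaves differed in 0 probe sets by limma without a block, with 94 at an unadjusted p under 0.05, and 1124 with the block within time. The named genes with the smallest p were FPPS1 (−0.29 ± 0.10), PR-5 (0.34 ± 0.13), RNALE (0.50 ± 0.19), the regulator GRAS10 (0.22 ± 0.09) and Xegip (−0.38 ± 0.16), and no list passed, though adjusted over the list alone 1 terpenoid gene was lower in NPA leaves. The replicate block called 0 and the block within time 1, HSP17.4, which was lower in NPA leaves by 0.51 ± 0.04 (adjusted p = 0.00157, named after its value was seen). Its means in water and NPA leaves were 5.83 and 5.65 at 3 dpt, 6.2 and 6 at 6 hpi, and 6 and 4.85 at 12 hpi. The averaged difference thus came mostly from 12 hpi. With the block within time 4 lists passed by camera. Heat shock genes stood lower in NPA leaves (adjusted p = 0.0105, and adjusted p = 0.2178 with an estimated correlation), as did the cell cycle list (adjusted p = 0.0344), while auxin, gibberellin and cytokinin genes (adjusted p = 0.0429) and photosynthesis genes (adjusted p = 0.05, under the threshold before rounding) stood higher. The last 3 each had adjusted p = 0.4766 with an estimated correlation.

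The interaction asks whether NPA changed the response to inoculation itself. From 3 dpt to 12 hpi the difference of NPA minus water fell for pathogenesis-related genes by a list mean of 0.71 (median −0.82, camera adjusted p = 2.66e-04, and adjusted p = 0.2943 with an estimated correlation), and for wound and jasmonate defence genes by 0.90 (median −0.91, adjusted p = 1.89e-04, and adjusted p = 0.0354 with an estimated correlation). It rose for cell wall genes by 0.24 (adjusted p = 0.0012, and adjusted p = 0.2943 with an estimated correlation), and fell for sugar genes by 0.41 (median −0.25, adjusted p = 0.0468, and adjusted p = 0.2943 with an estimated correlation). The named genes with the smallest p in this interaction were LAPA1 (−1.90 ± 0.45), LOC543602 (Eli3) (−1.59 ± 0.40, in none of these lists), LOC606710 (ppo) (−1.02 ± 0.29), CHI3 (−1.69 ± 0.55) and RBOH1 of the redox list (0.73 ± 0.22), each with an adjusted p of 1. Adjusted over the list alone the difference of NPA minus water fell for 2 wound genes. The GAPDH 3′ minus 5′ difference was 0.46 in water and 0.40 in NPA leaves at 3 dpt, and 0.727 and 0.863 at 12 hpi, where the arrays did not overlap. limma called 0 probe sets at 12 hpi, with 161 at an unadjusted p under 0.05, 0 with the replicate block and 4 with the block within time. With the block within time 1218 had an unadjusted p under 0.05.

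The pathogenesis-related interaction call at 12 hpi was lost without water replicate 2 (adjusted p = 0.0664) or NPA replicate 1 (0.1166) of 3 dpt. The cell wall call was lost without NPA replicate 3 of 3 dpt (0.0611), water replicate 3 of 12 hpi (0.0753) or NPA replicate 1 of 12 hpi (0.1074). For sugar genes it was lost without water replicate 2 (0.1024), water replicate 3 (0.0721), NPA replicate 1 (0.1955) or NPA replicate 3 (0.0607) of 3 dpt. It was also lost without water replicate 1 (0.0948), water replicate 3 (0.057), NPA replicate 1 (0.0695) or NPA replicate 2 (0.2001) of 12 hpi, with the replicate block (0.0856), with the block within time (0.122) and after cyclic loess (0.0583). Photosynthesis genes (adjusted p = 0.0917 without a block) passed with the block within time, higher in NPA leaves (adjusted p = 0.0453, and adjusted p = 0.2829 with an estimated correlation). The wound call held without each of the 12 arrays and with both blocks, at 0.0453 with the block within time, where it had adjusted p = 0.2829 with an estimated correlation. At 6 hpi no list passed in the interaction, with a smallest adjusted p of 0.6119. limma called 0 probe sets there, with 56 at an unadjusted p under 0.05, 0 with the replicate block and 1 with the block within time. With the block within time 626 had an unadjusted p under 0.05. The named genes with the smallest p were VPE5 (0.61 ± 0.21), APX1 (0.49 ± 0.18), AOS (−1.87 ± 0.73), THT1-3 (−1.30 ± 0.60) and ATG6 (0.33 ± 0.17). Of the NPA contrasts, including the interactions, fry called no list in its fit without a block.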

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

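The tests that leave out single arrays and that change the normalization were chosen before the result was seen, and the tests by replicate number and of swapped pairs after it. The estimated correlation was a setting chosen beforehand, and its use to test an explanation was chosen after.

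The difference between NPA and water leaves changed from 3 dpt to 12 hpi for 4 gene lists and, with the replicate block within time, for 4 single probe sets at 12 hpi and 1 at 6 hpi. Sugar genes had a list mean of −0.414 and cell wall genes of 0.239, each with adjusted p = 0.2943 with an estimated correlation, and the sugar call was also lost with the replicate block (0.0856), the block within time (0.122) and cyclic loess (0.0583). Over the same times the GAPDH 3′ minus 5′ difference was 0.46 and 0.727 in water and 0.40 and 0.863 in NPA leaves. With the block, HSP17.4 was at −0.977 (adjusted p = 0.0128), and 3 probe sets without a gene symbol at −0.67, −1.057 and −1.303 (adjusted p = 0.0489 each). At 6 hpi a probe set without a symbol was at −0.877 (adjusted p = 0.0225). These 5 probe sets were named after their values were seen. Swapping NPA and water within pairs gave as many probe sets at 12 hpi in 1 of 32 orders, the real one with 4 and the highest other with 3. That share is under 0.05, by a margin of 1 probe set and for a fit chosen after the data were seen. At 6 hpi 4 of 32 orders gave 1 or more, with 3 as the highest other, so chance was not excluded there, nor for the contrast averaged over the times.

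For pathogenesis-related genes (list mean −0.709) the list mean of NPA minus water was above 0 at 3 dpt and below 0 at 12 hpi in 6 of 6 comparisons by replicate number, but with an estimated correlation neither time passed (adjusted p = 0.748 and 0.4145), and the calls were lost without any of 3 of 6 arrays at 3 dpt (0.6602, 0.1643 and 0.7184) and 5 of 6 at 12 hpi (0.0716 to 0.4044). Phenylpropanoid and sugar genes had the same signs in 6 of 6. For the pathogenesis-related interaction the adjusted p was 6.38e-04 after cyclic loess of the deposited values, so the call did not depend on this further scaling. It starts from normalized values and cannot test the deposited normalization itself. Without NPA replicate 1 of 3 dpt the list mean was −0.45 and the adjusted p 0.1166, and without water replicate 2 of 3 dpt −0.45 and 0.0664. That met the criterion set beforehand for 1 array as the carrier. Without their partners, water replicate 1 and NPA replicate 2 of 3 dpt, the list mean was −1.09 and −0.94, so leaving out 1 array moved it either way. The change by replicate number was −0.48, −0.86 and −0.79 (SD 0.20). Its mean over the other 2 numbers was −0.82 without number 1, −0.64 without number 2 and −0.67 without number 3. The list mean thus stayed below 0 without each replicate number, by more than the SD. That comparison was chosen after the result was seen and the call itself was lost, so 1 array as its carrier stays open. It stays open that members vary together between pools of plants, since the adjusted p was 0.2943 with an estimated correlation, and an effect of NPA on these genes stays open too.

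Wound and jasmonate defence genes (list mean −0.897) moved the same way, with that sign in 5 of 6 comparisons by replicate number, but with an estimated correlation neither time passed (adjusted p = 0.088 and 0.3055). The highest adjusted p without 1 of the 12 arrays was 0.0064, which argues against a single array as the source. After cyclic loess of the deposited values the adjusted p was 1.67e-04, so the call did not depend on this further scaling, which again cannot test the deposited normalization itself. Members that vary together stay open, since with an estimated correlation the adjusted p was 0.0354 without a block and 0.2829 with the block within time.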

How the results depend on the processing

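The replicate block within time and all settings on it were chosen after the data were seen, as was leaving NSY out of the cell cycle list. The other settings were planned. The inoculation counts moved by less than 1.5 times under every setting but a fold of at least 2, which left 1998 and 3189 probe sets in water leaves and 1937 and 3032 in NPA leaves at 6 and 12 hpi. Without 1 array these counts ranged over 4172–4588, 5543–5685, 3906–4386 and 5433–5593. The 80 largest named changes kept direction and call in all 720 repeats. They were chosen from these same arrays for large changes without overlap, which favours that outcome. Of the 309 calls of named genes and list members over all comparisons, cyclic loess ended 5, array weights 2 and the replicate block 0 (it added 9), leaving out 1 array ended 73 of 1854, and no call turned. Between NPA and water at 12 hpi the count of 0 became 4 with the replicate block, 1 with median centring, 1 with array weights and 184 with the block within time, and 0 to 1 without 1 array. In each case the 1 was the same unnamed probe set, lower in NPA leaves, called without water replicate 2 and without NPA replicate 3. The block within time gave 1 averaged over the times, 1 in the interaction at 6 hpi and 4 in that at 12 hpi. With it, a trended and robust prior gave 306 at 12 hpi (179 of the 184 among them), and leaving out the pair of replicate 1, 2 or 3 gave 4, 3 or 38. Fewer pairs were then tested. Of the 25 list calls 1 held with an estimated correlation, 21 with the replicate block, 21 after cyclic loess and 12 with fry. The 12 were all calls after inoculation, and the 13 calls of NPA contrasts were lost in the fry run, which had no block. In the inoculation comparisons fry also called 37 list tests that camera had not called. The replicate block over all arrays ended the wound, photosynthesis and sugar calls at 12 hpi and the sugar interaction, and no other list call. For list: ethylene, NPA vs water at 3 dpt, camera pointed up (adjusted p = 0.911) but down without water replicate 2 (adjusted p = 0.0326), in a range of 0.0326 to 0.9457 without 1 array, and the cause was not tested. Scaling moved the median of all probe sets by at most 0.066. The number of arrays limits the precision throughout.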

Other observations

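The list tests and the test that leaves out 1 replicate pair were chosen before the result was seen, and the counts of other groupings and the tests of the other explanations below after it.

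In the auxin, gibberellin and cytokinin list 5 of 9 genes fell and 0 rose at 6 hpi in water leaves, and the same numbers at 12 hpi. The list did not pass as a group at 12 hpi (adjusted p = 0.2751) or at 6 hpi (adjusted p = 0.1639). IAA7, a repressor of auxin responses, was at −2.43 and −3.32, the gibberellin repressor GAI at −1.18 at both times and GA20OX1 at −3.87 and −5.98. In NPA leaves 4 fell at each time and 2, ARF3 and IAA3, rose at 12 hpi. The cell cycle list went both ways, with 3 of 10 rising and 2 falling at 6 hpi and 3 rising and 5 falling at 12 hpi in water leaves. At 12 hpi PCNA was at −3.81 and the kinase CDKB2 at −2.52, while CDKC rose by 0.97. Among the falls at 6 hpi, that of CDKB1 was lost without water replicate 1 (adjusted p = 0.156) or 2 (0.112) of 3 dpt or water replicate 1 (0.0656) or 3 (0.207) of 6 hpi, and after cyclic loess (0.098). At 6 hpi the median of that list (0.23) and its test pointed up and its mean (−0.18) down. Ribosomal protein genes fell in 3 of 5 cases at 6 hpi (median −0.42, adjusted p = 0.1639), and 1 rose and 1 fell at 12 hpi, where the rise of RPL37 was lost without water replicate 3 of 12 hpi (adjusted p = 0.0501). There the median was 0.13 and the mean −0.04. Clock and light genes rose in 2 and fell in 2 of 5 cases at 12 hpi in water leaves (adjusted p = 0.6987), with the photoreceptors CRY2 at 1.53 and CRY1A at −0.85 beside CO1.

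Among phosphate starvation genes the phosphate transporter PT1 rose by 4.29 and 4.51 in water leaves and by 4.05 and 3.86 in NPA leaves at 6 and 12 hpi. Without water replicate 2 of 3 dpt its rises in water leaves were 3.69 and 3.91. The acid phosphatase PAP1 fell by 1.10 in water and 0.92 in NPA leaves at 12 hpi. The list's median in water leaves was −0.06 at 6 hpi and −0.43 at 12 hpi, while its means were 0.73 and 0.53. Trichome and epidermis markers fell in 3 of 3 cases in each comparison, with ltpg1 at −5.36 and the lipid transfer proteins LE16 and TSW12 at −2.98 and −2.87 at 12 hpi in water leaves. LE16 and TSW12 also stand in the abscisic acid list, where NCED1, of abscisic acid synthesis, fell by 1.91 in water leaves at 12 hpi and ER5 did not pass. Of the vascular markers the sucrose transporters SUT4 and SUT2 did not pass in water leaves (0.09 and 0.44 at 12 hpi), though SUT2 at 12 hpi passed with the replicate block (adjusted p = 0.0207), with array weights (0.0477) and without water replicate 2 of 12 hpi (0.0253). PP2AC1, which like PP2Ac2 encodes a protein phosphatase subunit and not a phloem protein, fell by 0.46.

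Other groupings of the arrays were counted for each comparison. For inoculation the real grouping called 4821, 5911, 4630 and 5854 probe sets and each of the others 0, the real one being 1 of 10 in each case. The 10 splits of 3 against 3 arrays are too few for a share under 0.05. For NPA against water the real count was 0 at 3 dpt, 6 hpi and 12 hpi, so that 10 of 10 splits gave as many by construction and say nothing on chance. The highest others were 117, 0 and 40. The splits with 117 and 40 did not part all replicate pairs, and splits that did part them called 0. The arrays thus have a structure by replicate number, and their poly-A spike controls differed by it too, at 6.49 ± 0.13, 8.96 ± 0.11 and 7.72 ± 0.32 (log2, SD, n = 6) for replicates 1, 2 and 3. For the averaged contrast and the interactions at 6 and 12 hpi the real count was also 0, so that 100 of 100 drawn splits gave as many by construction, and the highest others were 8, 53 and 6. With the block within time the 184 probe sets at 12 hpi stood against a highest other of 1 in 4 swapped orders, the real one being 1 of them, which are too few for a share under 0.05. The averaged contrast with that block gave 1, and 14 of 100 orders gave as many, with a highest other of 25, so chance was not excluded.

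The 184 probe sets that differed between NPA and water leaves at 12 hpi, mostly lower in NPA leaves, were weighed against 3 explanations. Of probe sets called without a pair, the share with the same sign in the pair left out was 75% of 4 without the pair of replicate 1, 100% of 3 without that of replicate 2 and 97.4% of 38 without that of replicate 3, so 1 pair as the carrier of the calls stays open, since too few were called without pairs 1 and 2. RNA quality stays open, since the GAPDH 3′ minus 5′ difference was 0.137 higher in NPA leaves with no overlap of arrays, which cannot be told apart from the pretreatment, while the actin difference overlapped (−0.093 in NPA and −0.027 in water leaves). A less advanced response in NPA leaves may also contribute. Of the 184, 65.2% differed against their change from 3 dpt to 6 hpi in water leaves, against 51% of all probe sets. That is short of a cut-off of 75% set after the result was seen, which the explanation itself does not require. Over all probe sets the slope of NPA minus water at 12 hpi on the 6 hpi change was −0.034, −0.028 and −0.028 in the 3 pairs.

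The light-harvesting genes CAB4, CAB5 and CAB6A changed by −0.06, −0.57 and 0.00 at 6 hpi and by −5.07, −8.09 and −4.97 at 12 hpi in water leaves. The smallest of the falls after cyclic loess was −5.02, so the falls did not depend on this further scaling. It was run on normalized values and cannot test the deposited normalization itself. RNA quality is argued against by the GAPDH 3′ minus 5′ difference of water leaves, which changed by 0.02 from 6 to 12 hpi, within the range of the arrays. The mean change of −5.83 from 6 to 12 hpi could come from the light phase or clock hour or from the pathogen, which cannot be told apart, since the design holds no uninoculated leaves at those hours. In NPA leaves, where the GAPDH difference was 0.693 at 6 hpi and 0.863 at 12 hpi, the same genes fell at 12 hpi.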
